A study of Mus musculus with 18 samples.

How the data were processed

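Gene expression was measured on 18 microarrays, 3 in each of 6 groups. Per the labels, CD4 T cells without Foxp3 were isolated from pooled spleen and lymph nodes of male C57BL/6 mice aged 6 to 8 weeks and transduced with Foxp3 alone, Foxp3 with Pparg1 or Foxp3 with Pparg2. They were treated with pioglitazone or with its vehicle DMSO, and sorted with exclusion of CD11b, CD11c, B220, CD19, CD8, CD25 and NK1.1. Per the series' design text, cells of multiple mice were pooled, double-sorted and profiled in triplicate. RNA was extracted with TRIzol and labelled with the Affymetrix whole transcript sense kit, per the labels.

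The deposited values are probe set intensities that the authors made with RMA, which subtracts background, quantile normalizes and summarises probes. The submitters' processing notes name Affymetrix Power Tools and RMA, and the series' design text names RMA in GenePattern. Versions of these tools are not given in the sources used here. The intensities are on a linear scale, with array medians between 83.6 and 90.8, and were turned into log2 values here. No sequencing depth applies to arrays. The signal over background sets what is measured, and genes near the filter level have compressed changes.

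The table holds 25108 probe sets, of which 21157 carry a single gene symbol, 1341 several and 2610 none. The 21157 stand for 19531 genes, and for the 906 genes with several probe sets the one with the highest mean over all arrays was kept. A gene was tested if its log2 value lay above the 40th percentile of the array's single-gene probe sets in at least 3 of the 18 arrays. That percentile lay between 5.89 and 6.08, and 12318 genes were tested. Probe sets with no or several symbols were tested apart from these, and their counts are in the closing section. The gene names are those of the deposited platform table, and the Entrez numbers of 21074 of the single-gene probe sets are in the RefSeq gene table. No coordinates were used.

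Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group for the 6 groups, 12 residual degrees of freedom and moderated variances (7.53 prior degrees of freedom). The 12 comparisons are pioglitazone against vehicle within each of 3 kinds of cell, each isoform against Foxp3 alone within each treatment, Pparg1 against Pparg2 within each treatment, and 3 differences between drug responses. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 counted as past the threshold. Counts at least 1.5-fold are given beside it. The median standard error of a change was 0.108, a 95% half-width of 0.225 log2 units or 1.17-fold. For a difference between drug responses these were 0.152, 0.318 and 1.25-fold. Between arrays of the same group the SD of log2 differences ran from 0.144 to 0.322, and 0 pairs of arrays were identical.

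Gene lists were fixed before the data were examined, as were the groups, comparisons, filter, threshold, alternatives and the rule for naming genes. There were 26 lists of metabolic pathways, T cell states, signalling responses and markers of other cell types, written from general knowledge. They hold 513 symbols, of which 472 matched a single-gene probe set, and the other 41 were not analysed here. Each list was tested with camera of limma at a preset correlation of 0.01 and again with the correlation estimated for each list, with adjustment over the lists. List members were also adjusted over the list alone. Genes named in the text came from 3 sources. These are the 10 largest rises and 10 largest falls past the threshold without overlap between arrays (5 and 5 with no overlap rule for the differences between drug responses), the 4 members with the smallest p of each list past camera, and a fixed set. The fixed set is Pparg, Foxp3, Cd36, Fabp4, Gata3, Ccr2, Il10, Il1rl1 and Klrg1, and Il1rl1 matched no single-gene probe set. The groups of immunoglobulin probe sets, of B lineage genes apart from MHC class II and of small RNA genes were formed after the data were seen.

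Agreement of changes between comparisons that share Foxp3 arrays was set against 100 simulations with no effect. Alternatives covered the filter, the variance model, the replicate number as a block, the arrays in the fit, scaling, array weights, the probe set per gene, a fold limit and leaving out each of the 18 arrays. After the data were seen 2 were added. The first takes the mean level of small RNA genes (51 on the array, 46 tested) as a covariate, and the second leaves out the 3 arrays farthest under their group in that level.

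The pipeline was tested on simulated data with 200 changed genes among 12318. Noise was drawn independently for each gene and array, without the shared variation of the real arrays. In the pioglitazone comparison of Foxp3 cells it found 71.6% of the genes changed by 0.5 log2 units, 97.0% of those changed by 1 and 100% of those changed by 2, with 4.79% false calls. In the comparison of Pparg1 with Foxp3 in vehicle these were 68.7%, 100% and 100%, with 2.19% false calls. For a difference between drug responses they were 25.4%, 89.6% and 100%, with 5.92% false calls. The same list, shifted by 0.3, was found in 3 of 3 simulations, and 0 of 72 unshifted lists passed. With no correlation between genes in the simulation, this does not show how often camera calls lists falsely on real arrays.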

Results

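Gene expression was measured on 18 microarrays hybridised with RNA from mouse CD4 T cells that lacked Foxp3 when they were isolated and were then given Foxp3 by transduction. Foxp3 is the transcription factor that defines regulatory T cells. Some cells carried Foxp3 alone, and the others carried Foxp3 with Pparg1 or with Pparg2, the isoforms of the lipid-activated nuclear receptor Pparg. Each kind of cell was treated with pioglitazone, a drug that activates Pparg, or with its vehicle DMSO, which gives 6 groups of 3 arrays. The number of arrays per group limits the precision of each value. Levels are log2 intensities and changes are differences of log2 means ± standard error. Cells of several mice were pooled, and nothing says that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

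The transduced genes were read first in every array. Pparg lay between 5.75 and 6.01 in the 6 arrays with Foxp3 alone and between 9.69 and 10.72 in the 12 arrays with an isoform. Its mean was 5.93 ± 0.11 (SD, n = 3) with Foxp3 alone in vehicle, 10.01 ± 0.30 with Pparg1 and 9.87 ± 0.15 with Pparg2. In pioglitazone the means were 5.82 ± 0.07, 10.45 ± 0.26 and 10.03 ± 0.36. The Pparg probe set measures the gene as 1 value and does not tell the isoforms apart here. Foxp3 lay between 11.22 and 12.26 in all 18 arrays, and no comparison gave it an adjusted p under 0.05.

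**Figure D1:**
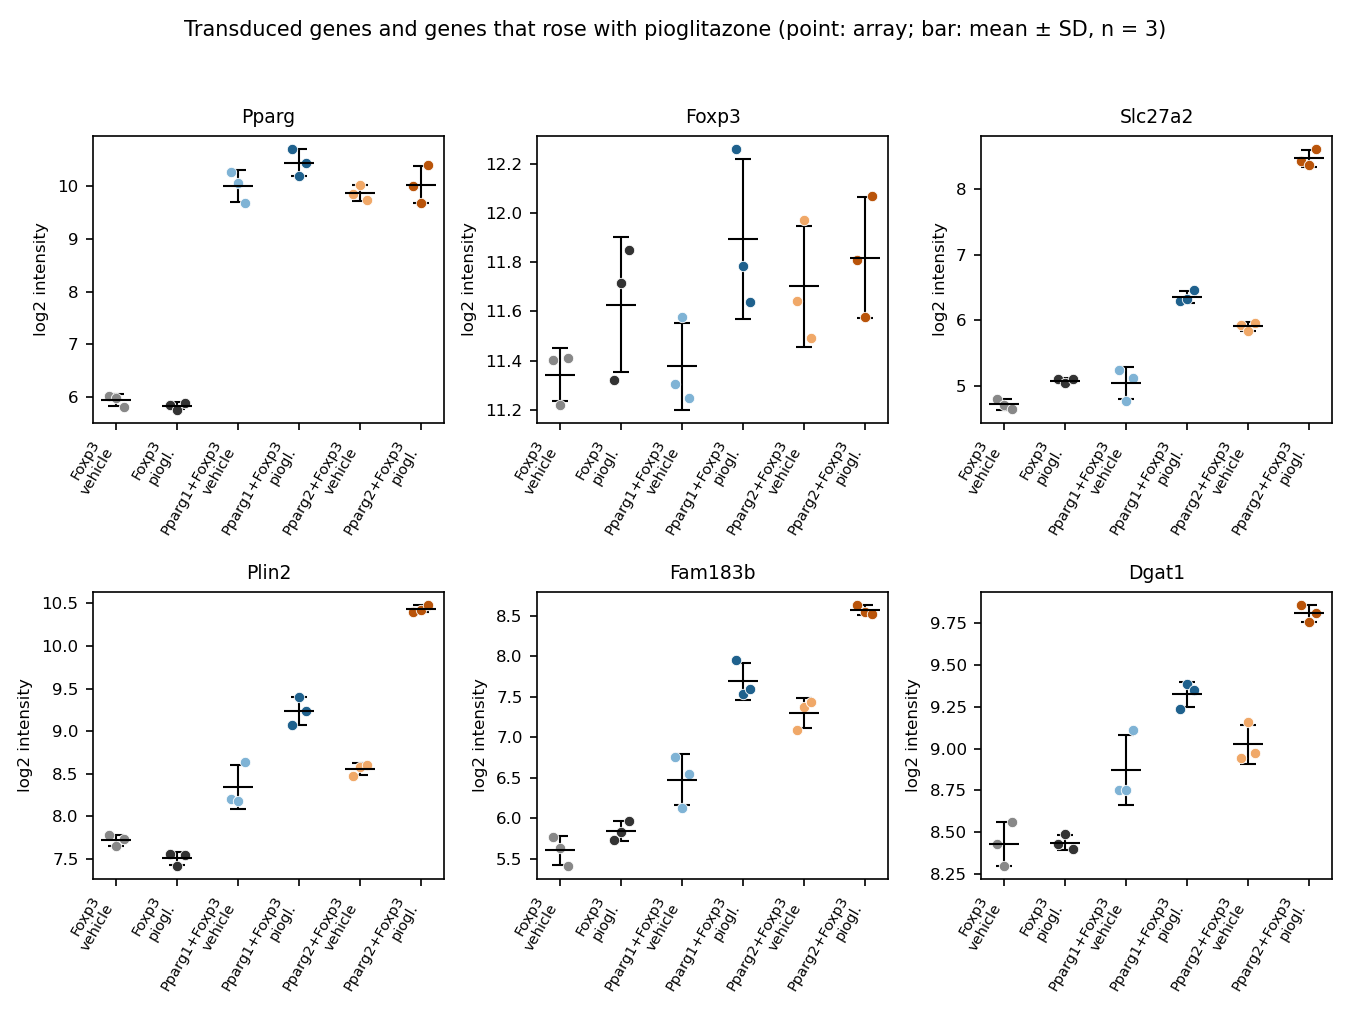
Log2 intensity (vertical axis) of Pparg, Foxp3, Slc27a2, Plin2, Fam183b and Dgat1 on each array of the 6 groups (horizontal axis), with points for arrays and bars for the mean ± SD of 3 arrays. Pparg ranges from 9.69 to 10.72 over the arrays with an isoform and from 5.75 to 6.01 over those with Foxp3 alone, and Slc27a2 has its highest mean, 8.48, with Pparg2 in pioglitazone.

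The first question was what pioglitazone does to cells with Foxp3 alone, which have no added receptor. No gene passed the test: limma gave 0 genes with an adjusted p under 0.05, against 1146 at an unadjusted p under 0.05, and the smallest adjusted p was 0.522. In simulated data with 200 changed genes and independent noise, the same comparison found 71.6% of changes of 0.5. That share does not carry over to a comparison with 0 calls, so changes of 0.5 or smaller can be missed, as can some larger ones. Slc27a2, which carries and activates very long chain fatty acids, had a mean of 4.71 ± 0.08 in vehicle and 5.08 ± 0.03 in pioglitazone (SD, n = 3). Plin2, which coats lipid droplets, had 7.72 ± 0.07 and 7.51 ± 0.08. Of the gene lists, oxidative phosphorylation was lower by camera as a list, with a mean change of -0.18 over 28 genes and an adjusted p of 6.8e-05, although 0 of its members passed the test. That call was lost with the correlation estimated from the data (adjusted p = 0.826 with an estimated correlation). Its members with the smallest p included Ndufv1 at -0.52 ± 0.15 and Ndufs3 at -0.60 ± 0.22, both subunits of respiratory complex I (adjusted p = 0.522). Fatty acid oxidation had a mean change of -0.12 over 22 genes with 0 members past the test (adjusted p = 0.0151, and 0.826 with an estimated correlation). The mean level of small nucleolar and other small RNA genes was 9.03 ± 0.25 in vehicle and 8.41 ± 0.45 in pioglitazone (SD, n = 3), the highest and lowest of the 6 groups. With that level as a covariate the mean change of oxidative phosphorylation was -0.007, and its list and fatty acid oxidation both had an adjusted p of 0.937. Without the 3 arrays lowest in small RNA for their group the adjusted p was 0.000798 for oxidative phosphorylation and 0.21 for fatty acid oxidation.

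The next question was what pioglitazone does to cells with Pparg1. It raised 3 genes and lowered 0. Slc27a2 rose by 1.32 ± 0.11 (adjusted p = 1.1e-06), from 5.04 ± 0.25, under the filter level, to 6.36 ± 0.09 (SD, n = 3). Fam183b, a gene of little known function, rose by 1.21 ± 0.14 (adjusted p = 0.00037), and Plin2 rose by 0.89 ± 0.11 (adjusted p = 0.00041). These 3 calls held in each of the 18 fits that left out 1 array. Cd36, a fatty acid receptor and known Pparg target, lay under the expression filter, and its change without the filter was 0.55 ± 0.19 (adjusted p = 0.991). Of the PPAR target and lipid droplet list, 1 of 20 tested genes rose, Plin2, and 1 rose when adjusted over the list alone. The list had a mean change of 0.11 (adjusted p = 0.00591, and 0.474 with an estimated correlation). The naive and central memory T cell list had a mean of 0.14 with 0 of 15 members past the test (adjusted p = 2.5e-05, and 0.474 with an estimated correlation). Glycolysis had a mean of -0.18 with 0 of 16 members past it, and Hk2, which starts glycolysis, stood at -0.53 ± 0.18 (adjusted p of the list 0.000724, and 0.594 with an estimated correlation). Without Pparg1 vehicle replicate 3 the mean of glycolysis did not keep its sign. In all, 5 lists were higher and 4 lower, of which 0 kept the call with an estimated correlation.

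In cells with Pparg2 the same question gave a larger response of the same lipid genes. Pioglitazone raised 8 genes and lowered 0. Slc27a2 rose by 2.57 ± 0.11 (adjusted p = 5.3e-12), from 5.91 ± 0.07 to 8.48 ± 0.13 (SD, n = 3) and thus from near the filter level, and Plin2 by 1.88 ± 0.11 (adjusted p = 1.7e-09), from 8.55 ± 0.07 to 10.44 ± 0.04. Fam183b rose by 1.27 ± 0.14 (adjusted p = 0.00012), and Dgat1, which catalyses the last step of triglyceride synthesis, by 0.78 ± 0.10 (adjusted p = 0.00064). The other 4 were Plk2 at 0.60, Arid3c at 0.50, Chst15 at 0.50 and Glul, which makes glutamine, at 0.49. Cd36 rose by 1.31 ± 0.19 when no filter was applied (adjusted p = 0.003), although its mean of 5.66 stayed under the filter level. Of the fatty acid oxidation list, 0 of 22 genes rose over all genes and 4 rose adjusted over the list alone. Its mean was 0.15 (adjusted p = 2.6e-09, and 0.108 with an estimated correlation), with Ehhadh, an enzyme of peroxisomal beta oxidation, at 0.58 ± 0.12 (adjusted p = 0.139). Of the PPAR target and lipid droplet list, 1 of 20 rose over all genes and 3 over the list alone (mean 0.14, adjusted p = 0.000598, and 0.128 with an estimated correlation). The interferon response list had a mean of 0.07 with 0 of 21 members past the test (adjusted p = 0.0094, and 0.456 with an estimated correlation). In all, 8 lists were higher and 2 lower, of which 0 kept the call with an estimated correlation. Slc27a2, Plin2, Fam183b and Dgat1 kept their calls in each of the 18 fits without 1 array, while Glul lost its call in 13, Plk2 and Chst15 in 12 each and Arid3c in 6. The count of 8 fell to 4 without any 1 of Pparg2 vehicle replicates 1 and 3 or Pparg2 pioglitazone replicates 1, 2 and 3. It fell to 5 without any 1 of Pparg1 vehicle replicate 2, Pparg2 vehicle replicate 2, Foxp3 vehicle replicates 2 and 3 or Foxp3 pioglitazone replicate 3.

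Whether the drug response differed between kinds of cell was tested directly. The response was larger with Pparg1 than with Foxp3 alone for 2 genes, Plin2 by 1.10 ± 0.15 (adjusted p = 0.00895) and Slc27a2 by 0.96 ± 0.15 (adjusted p = 0.0204). It was larger with Pparg2 than with Foxp3 alone for the same 2 genes, Slc27a2 by 2.20 ± 0.15 (adjusted p = 5.7e-08) and Plin2 by 2.09 ± 0.15 (adjusted p = 1.3e-07), with Dgat1 at 0.77 ± 0.14 (adjusted p = 0.0823). The response with Pparg1 was smaller than that with Pparg2, with a difference of -1.25 ± 0.15 for Slc27a2 (adjusted p = 0.000848), and the difference for Plin2 was -0.99 ± 0.15 (adjusted p = 0.02). The 3 genes that rose with Pparg1 all rose with Pparg2 as well, where independent lists would share 0.00195 genes. Across 12318 genes the responses with Pparg1 and Pparg2 correlated at 0.277, those with Foxp3 alone and Pparg1 at 0.448 and those with Foxp3 alone and Pparg2 at 0.141, and genes are not independent replicates. The mean small RNA level was 9.03 ± 0.25 in vehicle and 8.41 ± 0.45 in pioglitazone with Foxp3 alone (SD, n = 3). With Pparg1 it was 8.77 ± 0.15 and 8.53 ± 0.59, and with Pparg2 8.60 ± 0.35 and 8.57 ± 0.24. The correlations across genes do not separate a shared drug response from a shared shift of that level. The means of Slc27a2 with Foxp3 alone (4.71 and 5.08) and with Pparg1 in vehicle (5.04) lie under the filter level of 5.89 to 6.08, where changes are compressed, so its differences are not exact sizes. In the comparison of Pparg1 with Foxp3 alone the count of 2 fell to 0 without Pparg1 pioglitazone replicate 2, Foxp3 vehicle replicate 1 or Foxp3 pioglitazone replicate 2. It fell to 1 without Pparg1 pioglitazone replicate 3, Foxp3 vehicle replicate 2, or Foxp3 pioglitazone replicate 1 or 3. In the comparison of the isoforms Plin2 lost its call, which left 1 gene, without any 1 of Pparg1 pioglitazone replicates 1 and 3, Pparg2 vehicle replicates 1 and 2 or Pparg2 pioglitazone replicates 1, 2 and 3.

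The main question on the receptor was which genes differ when Pparg1 is added to Foxp3. In vehicle 348 genes passed, 315 higher and 33 lower, of which 193 changed at least 1.5-fold. Rises were ranked among genes past the threshold without overlap between arrays. After Pparg itself (4.08 ± 0.16, adjusted p = 3.2e-12) the 3 largest were those of the antigen presentation genes H2-Aa, Cd74 and H2-Ab1, and the B cell gene Ms4a1, Penk and Ccl3 came next. Probe sets of the immunoglobulin genes Igkv10-96 and Igkv4-91, not ranked here, stood at 3.03 and 2.93. The same comparison in pioglitazone gave 1.88 and 0.16 for them. H2-Aa, an MHC class II chain, rose by 2.57 ± 0.15 from 6.98 ± 0.45 to 9.56 ± 0.07 (SD, n = 3). Cd74, the invariant chain of MHC class II, rose by 2.31 ± 0.17, Ms4a1, which encodes CD20, by 2.15 ± 0.24, and Cd79a, a chain of the B cell receptor complex, by 1.78 ± 0.19. With Foxp3 alone Pparg (5.93), Ms4a1 (6.07) and Cd79a (5.77) lie at or under the filter level of 5.89 to 6.08, so these rises are not exact sizes. Of 17 tested B cell markers 16 rose and 0 fell, also when adjusted over the list alone, with a mean change of 1.30 (adjusted p = 0.000151 with an estimated correlation). The labels state that the sort removed cells with CD19 or B220, both surface proteins of B cells. Probe sets named for immunoglobulin genes, a set chosen after the data were seen, were higher for 29 of 29, with a median of 0.80 and 12 past the test.

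Genes of regulatory T cells and of those in visceral fat, where Pparg is known to act with Foxp3, rose with Pparg1 in the same arrays as the B cell markers. Of the visceral fat list of higher genes, 6 of 21 rose over all genes, 13 rose adjusted over the list alone and 0 fell, with a mean of 0.59 (adjusted p = 0.00104 with an estimated correlation). Pparg is itself a member, and without it the mean of the other 20 genes was 0.41 (p = 0.000573 with an estimated correlation). Its members included Scd1, which desaturates fatty acids, at 1.67 ± 0.18 (adjusted p = 1.2e-05), and Irf4, a transcription factor of effector regulatory T cells, at 1.18 ± 0.19 (adjusted p = 0.0018). The rise of Scd1 starts from a mean of 5.15, under the filter level, and is not an exact size. Ccr2 stood at 0.47 ± 0.13 (adjusted p = 0.0599) and Gata3 at 0.22 ± 0.11 (adjusted p = 0.428), while Il10, Klrg1 and Fabp4 lay under the filter and passed no test. Of the regulatory T cell core list, 6 of 22 rose over all genes and 11 adjusted over the list alone (mean 0.32, adjusted p = 0.0172 with an estimated correlation). Its members with the smallest p were the costimulatory receptor Tnfrsf9 at 1.07 ± 0.13 (adjusted p = 7.2e-05), Swap70 at 0.89 ± 0.13 and Capg at 0.74 ± 0.12. Irf4, Swap70 and Cd83 are also known to be expressed by B cells. The core list shares 4 tested genes with the T cell activation list and 1 with the visceral fat list of higher genes. That visceral fat list shares 3 with the activation list and 3 with fatty acid and triglyceride synthesis. The rises of these lists therefore partly count the same genes. Of the visceral fat list of lower genes, 3 of 13 fell over all genes and 4 over the list alone (mean -0.19, adjusted p = 0.0219 with an estimated correlation). They included S1pr1, the receptor by which T cells leave lymphoid tissue, at -0.42 ± 0.10. This list shares 11 of its 13 tested genes with the naive and central memory list, of which 3 of 15 fell (mean -0.21, adjusted p = 0.0787 with an estimated correlation). S1pr1 lost its call without Pparg1 vehicle replicate 1 or 3 or Foxp3 vehicle replicate 2 or 3.

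Proliferation and activation genes rose with Pparg1 as well, again beside the B cell marker rise of 1.30. Of 32 cell cycle genes 19 rose over all genes and 30 adjusted over the list alone, with 0 falling and a median of 0.62 (adjusted p = 0.0219 with an estimated correlation). Bub1, a mitotic checkpoint kinase, rose by 1.13 ± 0.18 (adjusted p = 0.0014), Nusap1, a spindle protein, by 0.94 ± 0.16 and the mitotic kinase Plk1 by 0.81 ± 0.14. Of 23 T cell activation and cytokine genes, 10 rose over all genes and 17 over the list alone (mean 0.43, adjusted p = 0.00645 with an estimated correlation), with Nr4a1, an early target of T cell receptor signals, at 1.01 ± 0.16. Of 20 NF-kappaB targets 7 rose and 9 over the list alone (mean 0.42, adjusted p = 0.00664 with an estimated correlation), with Cd83 at 1.42 ± 0.12 (adjusted p = 6.1e-07) and the chemokine Ccl3 at 2.08 ± 0.31 (adjusted p = 0.0008). Of 23 genes of the unfolded protein and amino acid stress response, 4 rose and 7 over the list alone (mean 0.27, adjusted p = 0.0373 with an estimated correlation), with Psat1 of serine synthesis at 0.83 ± 0.17, a call lost without Pparg1 vehicle replicate 3 or Foxp3 vehicle replicate 3. Glycolysis (mean 0.39, 3 of 16 rose, 9 over the list alone), cholesterol synthesis (mean 0.22, 2 of 20 rose, 3 over the list alone) and fatty acid and triglyceride synthesis (mean 0.21, 2 of 17 rose, 2 over the list alone) passed camera but lost the call, with adjusted p = 0.106, 0.054 and 0.0981 with an estimated correlation. So did Th1 and cytotoxic genes (4 of 18 rose, 4 over the list alone, adjusted p = 0.0981 with an estimated correlation) and Th2 genes (2 of 9 rose, 3 over the list alone, adjusted p = 0.06 with an estimated correlation). Hypoxia response genes (1 of 16 rose, 2 over the list alone) had an adjusted p of 0.259 with an estimated correlation. T cell identity genes had a mean of -0.06 with 0 of 16 past the test (adjusted p = 0.404 with an estimated correlation). Outside the lists Penk, which encodes the enkephalin precursor, rose by 2.15 ± 0.40 (adjusted p = 0.005), and the largest fall was that of Cpa3, a mast cell protease, at -1.47 ± 0.33 (adjusted p = 0.0168). The means of Bub1 with Foxp3 alone (6.00) and of Cpa3 with Pparg1 (4.69) lie at or under the filter level, so their changes are not exact sizes. Penk lost its call without Pparg1 vehicle replicate 3, and Cpa3 without Pparg1 vehicle replicate 3 or Foxp3 vehicle replicate 1 or 2. In all, 14 lists were higher and 3 lower, of which 8 kept the call with an estimated correlation. The count of 348 was 104 without Pparg1 vehicle replicate 3, 121 without Foxp3 vehicle replicate 2 and 137 without Foxp3 vehicle replicate 3. With arrays centred on their medians 256 genes were higher and 67 lower. With the small RNA level as a covariate 526 genes passed.

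**Figure D2:**
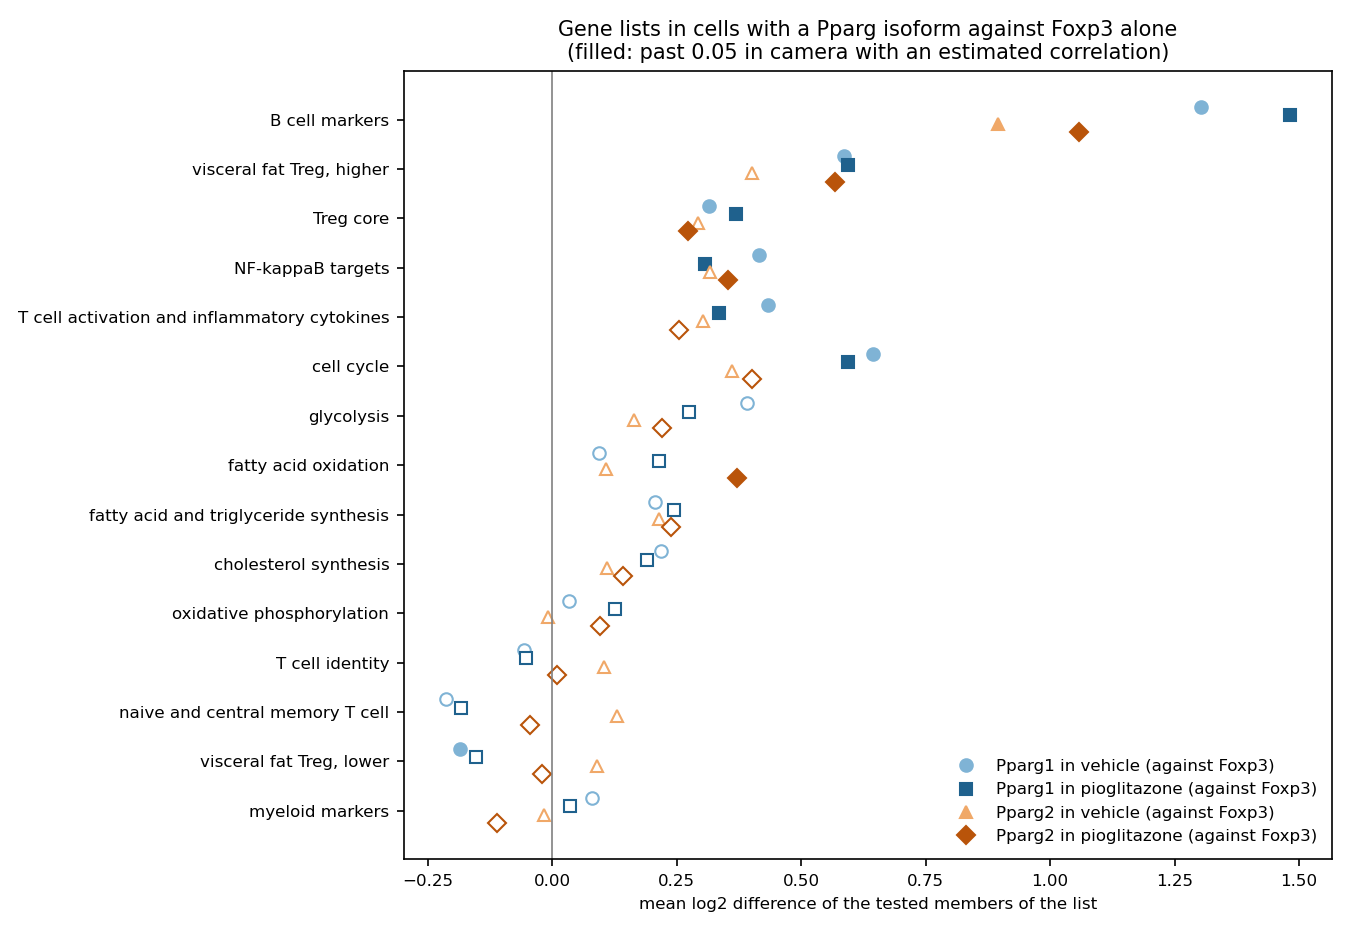
Mean log2 difference (horizontal axis) of the tested members of 15 gene lists (vertical axis) in cells with Pparg1 or Pparg2 against Foxp3 alone, in vehicle and in pioglitazone, with filled symbols for lists past 0.05 in camera with an estimated correlation. B cell markers have means of 1.30, 1.48, 0.90 and 1.06, and fatty acid oxidation is filled for Pparg2 in pioglitazone, at 0.37.

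In pioglitazone 273 genes differed between Pparg1 with Foxp3 and Foxp3 alone, 240 higher and 33 lower with Pparg1. Of these, 154 differed at least 1.5-fold. Pparg rose by 4.63 ± 0.16, H2-Aa by 3.07 ± 0.15, Ms4a1 by 2.67 ± 0.24 and Cd79a by 1.99 ± 0.19. With Foxp3 alone Pparg (5.82), Ms4a1 (5.56), Cd79a (5.66), Scd1 (5.11), Ccr6 (5.84) and Bub1 (5.95) lie at or under the filter level of 5.89 to 6.08, so their rises here are not exact sizes. Of 17 B cell markers 16 rose over all genes and over the list alone, with a mean of 1.48 (adjusted p = 5.7e-05 with an estimated correlation). Lipid genes rose in the same arrays: Scd1 by 1.85 ± 0.18 (adjusted p = 2.2e-06), Dgat1 by 0.88 ± 0.10 (adjusted p = 1.7e-05) and Etfb, which passes electrons from fatty acid oxidation to the respiratory chain, by 0.64 ± 0.10. Of 22 fatty acid oxidation genes 4 rose and 5 over the list alone (mean 0.21, adjusted p = 0.0616 with an estimated correlation), and of 17 genes of fatty acid and triglyceride synthesis 3 rose, also over the list alone (mean 0.25, adjusted p = 0.0616 with an estimated correlation). Cd36 without the filter rose by 1.10 ± 0.19 (adjusted p = 0.00319). Its means of 4.02 with Foxp3 alone and 5.12 with Pparg1 lie under the filter level, so this is not an exact size. Of 32 cell cycle genes 18 rose and 30 over the list alone (mean 0.59, adjusted p = 0.0284 with an estimated correlation), with Bub1 at 1.00 ± 0.18. The regulatory T cell core list had 7 of 22 genes higher and 12 over the list alone (mean 0.37, adjusted p = 0.00405 with an estimated correlation). The visceral fat list of higher genes had 5 of 21 and 12 over the list alone (mean 0.59, adjusted p = 0.000922 with an estimated correlation), and without Pparg the mean was 0.39 (p = 0.000547 with an estimated correlation). T cell activation genes rose for 5 of 23 and for 15 over the list alone (mean 0.33, adjusted p = 0.0136 with an estimated correlation), and NF-kappaB targets for 5 of 20 and for 7 over the list alone (mean 0.31, adjusted p = 0.0186 with an estimated correlation). All of these lists rose beside the B cell marker mean of 1.48. Of 7 Th17 genes 1 rose, the chemokine receptor Ccr6 at 1.00 ± 0.11 (adjusted p = 1.2e-05), which B cells also express, and the list had an adjusted p of 0.0794 with an estimated correlation. Oxidative phosphorylation had a mean of 0.13 with 0 of 28 past the test (adjusted p = 0.515 with an estimated correlation). The falls included the transcript A530021J07Rik at -0.82 ± 0.13 and St8sia6, a sialyltransferase, at -0.71 ± 0.12. In all, 15 lists were higher and 2 lower, of which 6 kept the call with an estimated correlation. The count of 273 was 110 without Foxp3 pioglitazone replicate 2, 131 without Pparg1 pioglitazone replicate 2 and 144 without Pparg1 pioglitazone replicate 3, and it was 415 without Pparg1 pioglitazone replicate 1. With arrays centred on their medians 199 genes were higher and 56 lower, quantile normalized again 232 and 58, and with array weights 473 and 289. With the small RNA level as a covariate 488 genes passed, and with only the groups of the comparison 162. Another split of the same arrays, which followed the small RNA level, gave 1517 genes, as described in the closing section.

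Pparg2 was set against Foxp3 alone with the same question. In vehicle 106 genes passed, 101 higher and 5 lower, and 65 changed at least 1.5-fold. Pparg rose by 3.95 ± 0.16, Fam183b by 1.70 ± 0.14 (adjusted p = 7.6e-07), H2-Aa by 1.83 ± 0.15, Ms4a1 by 1.45 ± 0.24 and Scd1 by 1.24 ± 0.18 (adjusted p = 0.0011). With Foxp3 alone Pparg (5.93), Fam183b (5.61), Ms4a1 (6.07) and Scd1 (5.15) lie at or under the filter level of 5.89 to 6.08, so these rises are not exact sizes. Of 17 B cell markers 10 rose over all genes and 14 over the list alone, with a mean of 0.90 (adjusted p = 0.00519 with an estimated correlation). This was the 1 list of the 8 past camera that kept its call with an estimated correlation. NF-kappaB targets rose for 5 of 20 genes and for 8 over the list alone, with the inhibitor Nfkbia at 0.80 ± 0.11 (adjusted p = 0.00068) and Nfkbiz at 0.62 ± 0.09, and the list had an adjusted p of 0.0623 with an estimated correlation. The visceral fat list of higher genes had 4 of 21 genes higher and 9 over the list alone, with 1 lower over the list alone (mean 0.40, adjusted p = 0.0623 with an estimated correlation), and without Pparg the mean was 0.22 (p = 0.0544 with an estimated correlation). The regulatory T cell core list had 0 of 22 past the test over all genes and 10 over the list alone (adjusted p = 0.0623 with an estimated correlation). The cell cycle list had 1 of 32 and 19 over the list alone (mean 0.36, adjusted p = 0.522 with an estimated correlation). These lists moved beside the B cell marker mean of 0.90. Hcst, an adaptor of activating receptors, fell by 0.54 and Tsc22d3, a glucocorticoid target, by 0.44, a call lost without Pparg2 vehicle replicate 3 or Foxp3 vehicle replicate 2 or 3. The count of 106 was 32 without Pparg2 vehicle replicate 2, 58 without Pparg2 vehicle replicate 1 and 198 without Pparg2 vehicle replicate 3. It was 32 without Foxp3 vehicle replicate 2, 41 without Foxp3 vehicle replicate 3, 160 without Foxp3 vehicle replicate 1 and 170 without Pparg1 pioglitazone replicate 1. Without the 3 arrays lowest in small RNA it was 49, and with arrays centred on their medians 46 genes were higher and 8 lower.

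With pioglitazone 180 genes differed between Pparg2 with Foxp3 and Foxp3 alone, 171 higher and 9 lower with Pparg2. Of these, 101 differed at least 1.5-fold. Pparg rose by 4.21 ± 0.16, Slc27a2 by 3.40 ± 0.11 (adjusted p = 2.5e-14), Plin2 by 2.93 ± 0.11 (adjusted p = 4.2e-13), Fam183b by 2.73 ± 0.14, H2-Aa by 2.44 ± 0.15 and Dgat1 by 1.37 ± 0.10 (adjusted p = 3.0e-08). With Foxp3 alone in pioglitazone Pparg (5.82), Slc27a2 (5.08) and Fam183b (5.84) lie under the filter level of 5.89 to 6.08, so these rises are not exact sizes. Of 22 fatty acid oxidation genes 8 rose over all genes and 14 over the list alone, and 0 fell, with a mean of 0.37 (adjusted p = 0.021 with an estimated correlation). They included the acyl-CoA dehydrogenases Acadl at 0.77 ± 0.09 (adjusted p = 6.4e-05) and Acadvl at 0.65 ± 0.09, Etfb at 0.75 ± 0.10 and the thiolase Acaa2 at 0.59 ± 0.08. Cd36 without the filter rose by 1.64 ± 0.19 (adjusted p = 3.0e-05). Its means of 4.02 with Foxp3 alone and 5.66 with Pparg2 lie under the filter level, so this is not an exact size. The visceral fat list of higher genes had 6 of 21 genes higher and 10 over the list alone (mean 0.57, adjusted p = 0.00262 with an estimated correlation). Without Pparg the mean of the other 20 genes was 0.39 (p = 0.00141 with an estimated correlation). Its member Cd69 stood at 0.98 ± 0.16. The regulatory T cell core list had 5 of 22 higher and 10 over the list alone (mean 0.27, adjusted p = 0.0387 with an estimated correlation), with Capg at 0.75 ± 0.12. NF-kappaB targets had 6 of 20 higher and 10 over the list alone (mean 0.35, adjusted p = 0.021 with an estimated correlation), with Nfkbia at 0.91 ± 0.11. Of 17 B cell markers 12 rose and 16 over the list alone, with a mean of 1.06 beside those of the other lists (adjusted p = 0.00113 with an estimated correlation). The cell cycle list had 2 of 32 higher and 20 over the list alone (mean 0.40, adjusted p = 0.168 with an estimated correlation). T cell activation genes had 3 of 23 higher and 9 over the list alone (adjusted p = 0.119 with an estimated correlation). Plin4, another lipid droplet protein, stood among the falls at -0.45 ± 0.11 (adjusted p = 0.0439), a call lost in 11 of the 18 fits without 1 array. In all, 13 lists were higher and 0 lower, of which 5 kept the call with an estimated correlation. The count of 180 was 108 without Pparg2 pioglitazone replicate 1 and 113 without Pparg2 pioglitazone replicate 2. With arrays centred on their medians 116 genes were higher and 26 lower.

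The receptor comparisons were then set side by side. In both treatments and with both isoforms 45 genes were higher and 0 lower in common, and 10 of the 45 are on the B cell marker list. Pparg is 1 of the others. Ly86, Ly6d, Cd24a, Pik3ap1, Mef2c, Pld4, Cybb, Rnase6 and Ifi30 are also among them and are known from B cells or other antigen-presenting cells, though not on that list. The rest include the lipid genes Plin2, Scd1, Dgat1 and Acadl, and Fam183b, Plk2, Xbp1, Gzmb, Nfkbia and Cd83. For Pparg1, 167 genes were higher in both vehicle and pioglitazone where independent lists would share 6.14, and for Pparg2 62 where 1.40 would be shared. The isoforms shared 70 higher genes in vehicle (2.58 for independent lists) and 96 in pioglitazone (3.33 for independent lists). The isoform lists of a treatment use the same Foxp3 arrays, so the values for independent lists are not those with no effect. Their changes correlated across genes at 0.673 in vehicle and 0.762 in pioglitazone, against 0.499 and 0.501 simulated with no effect and the same Foxp3 arrays. The covariances were 0.0254 and 0.0278, against 0.00699 and 0.00702 simulated. The 3 Foxp3 arrays of a treatment are too few to be split into separate controls, so part of the excess may come from the shared arrays.

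The last question was whether the isoforms differ from each other. In vehicle 8 genes differed. Ccl3 was higher with Pparg1 by 1.92 ± 0.31 (adjusted p = 0.0174), H2-Ab1 by 0.79 ± 0.12, Fcmr, the IgM receptor of B cells, by 0.61 ± 0.10 and Egr2, induced by T cell receptor signals, by 0.59 ± 0.11. Slc27a2 was lower with Pparg1, at -0.87 ± 0.11 (adjusted p = 0.00111) with its Pparg1 mean of 5.04 under the filter level, as were Fam183b at -0.82 ± 0.14, Plcxd2 at -0.49 ± 0.08 and Txnip, an inhibitor of glucose uptake, at -0.46 ± 0.08. In pioglitazone 5 genes differed, with Slc27a2 at -2.11 ± 0.11 (adjusted p = 2.1e-10), Plin2 at -1.20 ± 0.11 (adjusted p = 4.8e-06), Fam183b at -0.88 ± 0.14, the phosphodiesterase Pde7a at -0.56 ± 0.10 and H2-Ab1 at 0.66 ± 0.12. Pparg itself differed by 0.14 ± 0.16 in vehicle and 0.42 ± 0.16 in pioglitazone (adjusted p = 0.765 and 0.758). B cell markers were higher with Pparg1 as a list, by a mean of 0.41 in vehicle (1 of 17 higher, 9 over the list alone, adjusted p = 0.0161 with an estimated correlation) and 0.42 in pioglitazone (1 of 17, 10 over the list alone, adjusted p = 0.00899 with an estimated correlation). Beside that, in vehicle, the visceral fat list of higher genes had a mean of 0.18 (0 of 21 higher, 1 over the list alone, adjusted p = 0.0496 with an estimated correlation). The visceral fat list of lower genes had a mean of -0.28 (0 of 13 lower, 9 over the list alone, adjusted p = 0.0161 with an estimated correlation). The naive and central memory list had a mean of -0.34 (0 of 15 lower, 13 over the list alone, adjusted p = 0.0496 with an estimated correlation). Cell cycle genes were higher in vehicle by a mean of 0.28 (0 of 32 past the test, 5 over the list alone, adjusted p = 0.199 with an estimated correlation). Fatty acid oxidation in pioglitazone had a mean of -0.16 (0 of 22, 3 lower over the list alone, adjusted p = 0.251 with an estimated correlation), with Ehhadh at -0.66 ± 0.12 (adjusted p = 0.058). Slc27a2 kept its call in both treatments, and Plin2 in pioglitazone, in each of the 18 fits without 1 array. The count of 8 was 1 without Pparg1 vehicle replicate 2, Pparg1 vehicle replicate 3 or Pparg2 vehicle replicate 3, and 5 without Pparg2 vehicle replicate 2. The count of 5 was 2 without Pparg1 pioglitazone replicate 2 or Pparg2 pioglitazone replicate 2 or 3, and 8 without Foxp3 pioglitazone replicate 3. It was 3 without any 1 of Pparg1 vehicle replicate 2, Pparg1 pioglitazone replicates 1 and 3, Pparg2 vehicle replicate 1 and Pparg2 pioglitazone replicate 1. With arrays centred on their medians, or quantile normalized again, 0 genes were higher and 2 lower with Pparg1 in pioglitazone.

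**Figure D3:**
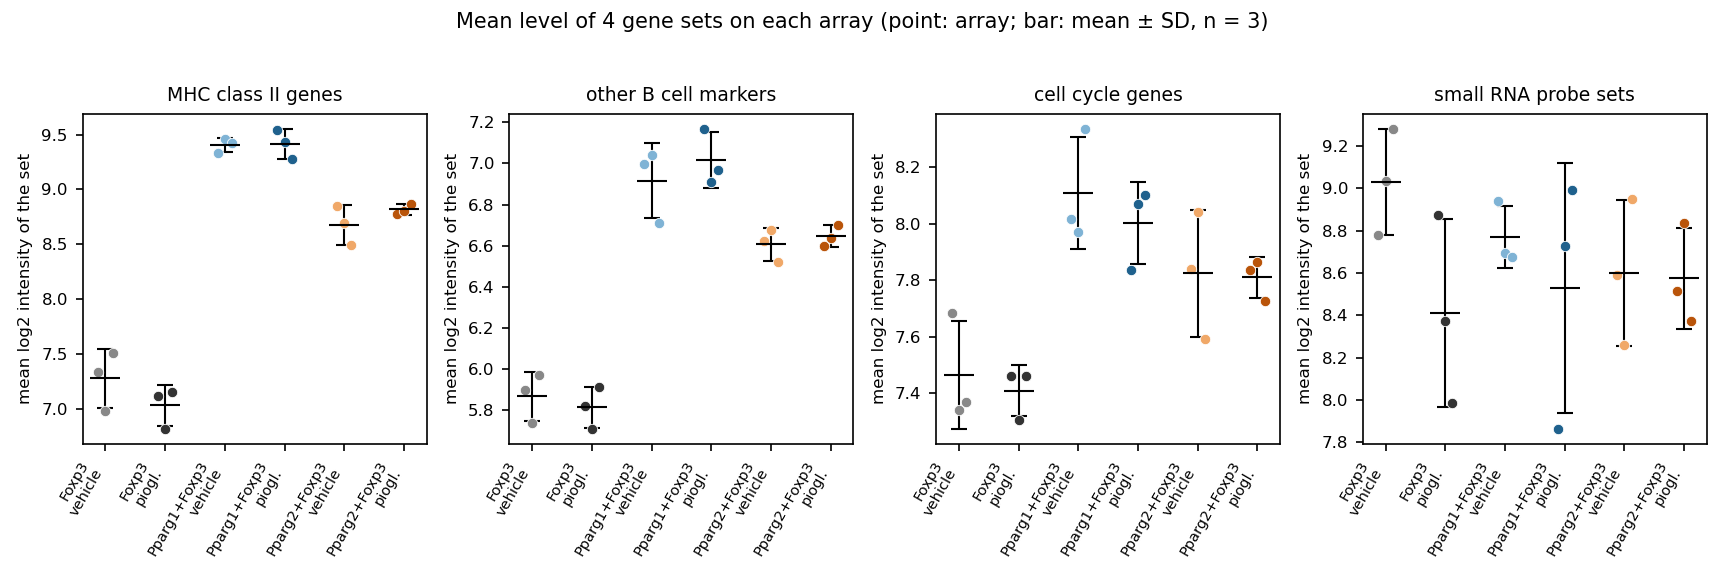
Mean log2 intensity (vertical axis) of MHC class II genes, the other B cell markers, cell cycle genes and small RNA probe sets on each array of the 6 groups (horizontal axis), with points for arrays and bars for the mean ± SD of 3 arrays. The 3 left panels are higher with Pparg1 than with Foxp3 alone in both treatments, with cell cycle means of 0.64 and 0.59 in the test, and small RNA spreads widely within groups.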

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

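The tests of myeloid markers, of B lineage genes outside MHC class II and of the relations between B lineage levels and those of other lists were chosen only after the results were seen. The within-group relation of small RNA and respiratory chain levels had no prediction written. The other tests were written before their values were computed.

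The drug response differed between kinds of cell by a direct test for 2 genes of lipid handling. Against Foxp3 alone the response with Pparg1 was larger by 1.10 for Plin2 and 0.96 for Slc27a2, and that with Pparg2 by 2.09 and 2.20. The response with Pparg1 minus that with Pparg2 was -0.99 for Plin2 and -1.25 for Slc27a2. Over 100 splits of the arrays, the real one included, 4 gave at least the 2 genes seen for Pparg1 (highest other 2). That is under the 0.05 share, as predicted if chance is not the cause, but it is not adjusted over these comparisons. The count of 2 was also 0 with only the groups of the comparison, so chance is not excluded there. For Pparg2, 10 of 100 splits gave at least 2 genes (highest other 4), and for the difference between isoforms 8 of 100 (highest other 24). Each split regrouped the 2 kinds of cell separately, so it could keep the real drug grouping in 1 kind and still carry its response. The shares of 10 and 8 therefore cannot tell whether chance explains the number of genes. By limma the 2 genes seen have adjusted p from 5.7e-08 to 0.02 in these comparisons.

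By the same test at the preset correlation, several gene lists responded differently to the drug. With Pparg1 against Foxp3 alone these were fatty acid oxidation (0.12) and B cell markers (0.18). With Pparg2 against Foxp3 alone they were fatty acid oxidation (0.26), the visceral fat list of higher genes (0.17), naive and central memory genes (-0.17) and B cell markers (0.16). For Pparg1 minus Pparg2 they were fatty acid oxidation (-0.14), the visceral fat lists of higher genes (-0.16) and lower genes (0.14), Th1 and cytotoxic genes (-0.18), NF-kappaB targets (-0.15), naive and central memory genes (0.20), cell cycle (-0.0918), glycolysis (-0.17), unfolded protein and amino acid stress (-0.14), hypoxia response (-0.19) and T cell identity (0.10). None kept its call with an estimated correlation, where the smallest adjusted p was 0.146.

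Probe sets with no or several gene names also passed the threshold, of 2390 tested. There were 34 with Pparg1 in vehicle, 41 with Pparg1 in pioglitazone, 9 with Pparg2 in vehicle, 17 with Pparg2 in pioglitazone and 6 between the isoforms in vehicle. Those with gene names include the MHC class II genes H2-DMb1 and H2-DMb2 at 1.23 ± 0.11 and lambda light chains at 1.68 and 1.79, with Pparg1 in vehicle.

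The rise of B cell markers with Pparg was weighed first. If B cells remained in the sorted Pparg samples, the excess over the Foxp3 arrays would have the same ratio of Pparg1 to Pparg2 for MHC class II as for B lineage genes. That ratio was 2.04 in vehicle (10th to 90th percentile of B lineage genes 1.03 to 2.13) and 1.74 in pioglitazone (1.31 to 2.66), which is consistent with such cells. The test separates few sets. Cell cycle (1.77 and 1.62), T cell activation (1.45 and 1.54) and regulatory T cell core genes (1.45 and 1.38) lie within these percentiles. NF-kappaB targets lie within them in vehicle alone (1.11 over 5 genes and 1.03 over 6). Fatty acid oxidation lies below them (0.98 over 2 genes and 0.48 over 7). Only members above a fold limit with both isoforms entered a ratio, so some ratios rest on few genes. Induction of MHC class II in the T cells alone is not supported, since B lineage genes outside it had a median change of 0.915 and 12 of 13 rose, nor are myeloid or dendritic cells as the whole source, with a median of 0.120 over 6 markers. A wider B lineage program switched on by Pparg in the T cells was not tested, and the samples give no way to separate it from carried-over cells.

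A sort that excludes CD19 and B220, as the labels state was done, would remove most B cells, so any that remain passed it. In the Foxp3 vehicle arrays 7 of 17 B cell markers already lie above the filter level, and with Pparg1 in vehicle 16 do. Those with the highest intensity with Pparg1 in vehicle were Cd74 (9.90, and 7.59 with Foxp3), H2-Aa (9.56 and 6.98), H2-Ab1 (9.30 and 7.07) and H2-Eb1 (8.86 and 7.47), although levels of different probe sets compare only roughly. The B cell list shares no tested gene with another list, although Cd83, Swap70, Irf4 and Ccr6 are known to be expressed by B cells.

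The rise of cell cycle and activation genes with Pparg1 was weighed second. Within groups the B lineage and cell cycle levels of the 18 arrays correlated at -0.214 (permutation p = 0.527), those of B lineage and activation genes at 0.178 (p = 0.616) and those of B lineage and regulatory T cell core genes at 0.443 (p = 0.0816). With 3 arrays per group these values neither support nor exclude carried-over B cells as the source. With the small RNA level as a covariate 22 cell cycle genes passed against 19 without it, so their count did not fall, as predicted if RNA composition is not the cause. The covariate also raised the count over all genes from 348 to 526, so this count cannot exclude RNA composition as part of the rise. A biological effect of Pparg1 on proliferation may explain the rise but was not separated from a difference in culture or in the timing of the sort.

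The lower respiratory chain list with pioglitazone in Foxp3 cells was weighed last. With the small RNA level as a covariate its adjusted p was 0.937, and without the 3 arrays low in small RNA it was 0.000798. Within groups the small RNA and respiratory chain levels correlated at 0.827 (permutation p = 0.00162, adjusted p = 0.00972). This is consistent with a difference in RNA composition between arrays, which could be technical. The covariate is partly confounded with the drug, since small RNA is lower with it, so a drug effect is not excluded.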

How the results depend on the processing

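Across all alternatives, 5681 values of named genes kept their direction and side of the threshold, 748 became weaker, 13 stronger and 5 reversed. Of list calls 3013 were kept, 284 lost and 8 reversed. Fits without 1 array gave 3389 of the kept values and 1922 of the kept list calls. Many such fits drop an array outside the comparison, which leaves the change itself the same and alters only its variance. With the correlation estimated per list 25 of 114 list calls were kept. Numbers of genes past the threshold moved more, and the cause was not tested unless stated. With no filter pioglitazone in Pparg2 cells gave 5 genes (8 otherwise) and Pparg1 against Pparg2 in pioglitazone 3 (5 otherwise), where more genes were tested. Replicate numbers do not pair the arrays: of 45 pairs of arrays with the same number 15 had residuals correlated over 0.1 (range -0.69 to 0.47), and 2 of 18 arrays were closest to their own number. As a replicate block the numbers gave 4 genes for pioglitazone in Pparg2 cells, 58 for Pparg2 in vehicle and 2 for Pparg1 against Pparg2 in pioglitazone. With only the groups of the comparison, which leaves fewer arrays, the counts were 5 for pioglitazone in Pparg2 cells, 162 for Pparg1 in pioglitazone, 5 and 2 for Pparg1 against Pparg2 in vehicle and in pioglitazone, 0 for the interaction of Pparg1 and the drug and 1 for the difference between isoforms in drug effect. Median-centred arrays gave 54 for Pparg2 in vehicle and 2 for Pparg1 against Pparg2 in pioglitazone, and quantile normalized again 5 and 2 for Pparg1 against Pparg2 in vehicle and pioglitazone, 1 for the Pparg1 interaction and 5 for the Pparg2 interaction. Array weights gave 40 for pioglitazone in Pparg2 cells, 762 for Pparg1 in pioglitazone, 387 and 517 for Pparg2 in vehicle and pioglitazone, 30 and 461 for Pparg1 against Pparg2 and 6 for the Pparg2 interaction. All single-gene probe sets gave 5 for pioglitazone in Pparg2 cells. With the small RNA covariate the counts were 17 for pioglitazone in Pparg2 cells, 526 and 488 for Pparg1 in vehicle and pioglitazone, 402 for Pparg2 in pioglitazone and 44 and 20 for Pparg1 against Pparg2. With the 3 arrays low in small RNA left out they were 49 for Pparg2 in vehicle, 8 for Pparg1 against Pparg2 in pioglitazone, 1 for the Pparg1 interaction and 1 for the difference between isoforms in drug effect. At least 1.5-fold left 5 for pioglitazone in Pparg2 cells, 193 and 154 for Pparg1 and 65 and 101 for Pparg2, by the fold limit itself. Foxp3 in Pparg1 in vehicle (0.03) was -0.00619 with median-centred arrays and -0.12 with the covariate, and oxidative phosphorylation with pioglitazone in Pparg1 cells (-0.08) was 0.0202 with the 3 arrays left out.

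Leave-one-out fits gave ranges of 4 to 11 for pioglitazone in Pparg2 cells, 3 to 4 in Pparg1 cells and 0 in Foxp3 cells, 104 to 390 and 110 to 415 for Pparg1 in vehicle and pioglitazone, 32 to 198 and 108 to 219 for Pparg2, 1 to 11 and 2 to 8 for Pparg1 against Pparg2, 0 to 2 and 2 to 3 for the interactions of Pparg1 and Pparg2 and 1 to 2 for the difference between isoforms in drug effect. Direction changed in some for Foxp3 in Pparg1 in vehicle (-0.0667 to 0.10) and Pparg in pioglitazone in Pparg2+Foxp3 (-0.0266 to 0.33). It also changed for lists with pioglitazone in Pparg1 cells: cell cycle (-0.18 to 0.00832), glycolysis (-0.30 to 0.0173), hypoxia response (-0.19 to 0.018) and oxidative phosphorylation (-0.19 to 0.0202). In the difference between isoforms in drug effect it changed for cell cycle (-0.20 to 0.0251) and glycolysis (-0.29 to 0.0269). Genes near the filter level, such as Cd36, are limited by signal over background.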

Other observations

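The splits of arrays were set before their values were computed, while the makeup of the highest split was examined only after the result was seen, so these tests of its cause were chosen afterwards.

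Immunoglobulin probe sets were mostly higher with the isoforms, and with the drug none of them passed the threshold. Of 29, 29 were higher with Pparg1 in vehicle (median 0.80, 12 past the threshold), 29 in pioglitazone (1.00, 14 past it), 24 with Pparg2 in vehicle (0.40, 1 past it) and 25 in pioglitazone (0.68, 7 past it). With pioglitazone against vehicle 14, 16 and 17 were higher in cells with Foxp3, Pparg1 and Pparg2, with 0 past it. This does not show that the treatments are alike. Against Foxp3 alone, Pparg1 gave 2.93 in vehicle and 0.16 in pioglitazone for Igkv4-91. For a probe set of Igkv9-120 it gave 1.08 and 1.94. Several of the 29 are named for the same genes. MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 rose for 4 of 4 with each isoform, with medians of 2.27 and 2.56 for Pparg1 and 1.41 and 1.83 for Pparg2. B lineage genes outside them rose for 12 and 12 of 13 with Pparg1 and for 6 and 8 with Pparg2. Within groups the levels of these 2 sets correlated at 0.623 (permutation p = 0.0135, adjusted p = 0.0406), and by rank at 0.643 (adjusted p = 0.0505), which does not pass 0.05.

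Each comparison of 2 groups was set against the 10 possible splits of its 6 arrays, the real one included, which are too few for a share under 0.05. Pioglitazone in Foxp3 cells had 10 of 10 splits with at least its 0 genes (highest other 0), in Pparg1 cells 1 with at least 3 (highest other 0) and in Pparg2 cells 1 with at least 8 (highest other 0). Pparg1 in vehicle had 1 with at least 348 (highest other 0) and in pioglitazone 2 with at least 273 (highest other 1517). Pparg2 in vehicle had 1 with at least 106 (highest other 16) and in pioglitazone 1 with at least 180 (highest other 0). Pparg1 against Pparg2 had 1 with at least 8 in vehicle (highest other 0) and 1 with at least 5 in pioglitazone (highest other 0).

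The split with 1517 genes set Pparg1 pioglitazone replicate 1 and Foxp3 pioglitazone replicates 2 and 3 against the other 3 arrays. Their small RNA levels were 7.86, 8.37 and 7.99 against 8.73, 8.99 and 8.88, so it points to a structure of the samples that runs across groups. Over all arrays the first component of the residuals held 37.8% of their variance. It correlated at -0.966 with the small RNA level taken as the deviation from the group mean. Of its 40 most extreme loadings at the same end, 23 were small RNA genes. The component was computed from genes that include these, so the correlation is not an independent link to RNA composition.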
